A study of Cupriavidus metallidurans with 27 samples.

How the data were processed

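Total RNA of *Cupriavidus metallidurans*, a metal-resistant soil bacterium, was hybridised to 27 1-colour Agilent arrays. Per the labels, 3 strains (AE104, the mutant delta e4, here De4, and the mutant delta e4 with a zupT deletion, here De4zupT) were left untreated or given 100 µM Zn or 50 µM EDTA for 10 min at 100 Klett units, a measure of culture turbidity, with 3 replicates in each of the 9 groups. The labels do not state whether replicates were independent cultures, so p-values measure the spread between these samples. AE104 is known as a plasmid-free derivative of the type strain, and delta e4 as a strain that lacks the efflux genes zntA, cadA, dmeF and fieF; this is background knowledge, not in the labels.

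The deposited intensities were written by Feature Extraction 10.7.3.1, which subtracted the local background and gave a processed signal per spot, per the file headers. The authors also deposited a value table of 9735 probes on a linear intensity scale, whose columns followed each array's processed signal divided by a mean of that array, with medians between 0.084 and 0.119 and 78 values at or below 0; which probes entered that mean, and the tool that made the table, are not given in the sources used here. It served as an alternative. Each array held 15743 features, of which 15207 were not controls. These carried 10100 names, of which 3419 were intergenic, 329 were gene symbols and 6352 were locus tags (339 of these had more than 4 digits). Every product description in the files read as unknown, and the files do not pair locus tags with symbols. Tags for zntA (Rmet_4594), cadA (Rmet_2303), dmeF (Rmet_0198), fieF (Rmet_3406), zupT (Rmet_2621) and zur (Rmet_0128) were written down from background knowledge before the data were examined; other tags are printed without names.

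Control spots and 123 spots marked as outliers on single arrays were left out, no spot was saturated, and the processed signal was put on a log2 scale and reduced by each array's 75th percentile. Spots of a probe, and then the probes of a gene, were averaged. A gene was tested where at least 1 probe was well above background, by the scanner software's own mark, on all 3 arrays of at least 1 group: 6263 genes were tested and 418 were not. Linear models with 1 mean per group over all 27 arrays (18 residual degrees of freedom) were fitted with limma 3.58.1 in R 4.3.3, with moderated statistics and a two-sided test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1; "rose", "fell", "higher" and "lower" refer to such calls, and ± is the SD over 3 arrays. The 13 contrasts were Zn and EDTA against untreated in each strain, the 3 pairs of untreated strains, and 4 differences between effects. The probes of a gene called in a comparison never moved in opposite directions by more than 0.5 each, counted over genes with 2 probes. They lay over log2 1 apart in 20 of 237 such genes for De4 against AE104, 22 of 248 for De4zupT against AE104 and 5 of 20 for EDTA in De4zupT. In each other comparison of groups this held for 4 genes or fewer. Where a gene was not well above background on any array of a group, its fold is a lower bound: the bright group's mean against the mean over the dim group's arrays of the higher of the gene's own signal and the lowest signal well above background on that array, printed as "at least N-fold".

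Gene lists, thresholds, the tests and the rule for naming genes were fixed before the data were examined. The rule took the 8 largest rises and falls per comparison with separated arrays (5 per direction for differences of effects), up to 4 members of each list past its test, and the 6 tags above; because tags have no names, at most 2 rising and 2 falling tags are printed per comparison, together with tags said to be chosen afterwards. The lists were to be built from product text, which the files lack, so 26 of 31 planned lists could not be built from it. Of these and the others, 15 were built on symbols and tags from the planned patterns, and 7 lists on symbols were added after the names, but not the values, had been read. At least 5 tested members were present in 16 lists. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether members move on balance in 1 direction. Overlaps of calls used a one-sided exact hypergeometric test. On simulated data for Zn in De4 over 6263 genes, the model recovered 98.5%, 100% and 98.5% of genes changed by log2 1.5, 2 and 3, with 2 unchanged genes called; for the difference of the Zn effect between De4 and AE104 it recovered 95.5%, 98.5% and 97.0%. With no gene changed, 0 were called for Zn in AE104, and a list of genes lowered by 1 was found with 0 of the others. The simulated genes were independent of each other and free of slide effects, so false list calls from correlated genes could not be seen.

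The arrays lay on 4 slides that partly follow the strains. Slide 1 held AE104 untreated and Zn and 1 AE104 EDTA array; slide 2 held 1 AE104 EDTA array and the De4zupT EDTA arrays; slide 3 held 1 AE104 EDTA array, De4 untreated and Zn, and 1 De4 EDTA array; slide 4 held the other 2 De4 EDTA arrays and De4zupT untreated and Zn. Each Zn comparison lay within 1 slide. The other comparisons did not, and their counts and some of their values with slide as a block are given beside them. The slide term had an adjusted p under 0.05 for 118 of the 6263 genes and an unadjusted p under 0.05 for 848. Only the EDTA groups of AE104 and De4 span slides, so this test has little power and the small count does not show that slides matter little. Alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, the value table, other filters on dim probes, the brightest probe of a gene, no fold minimum, an intensity trend in the variance, only the groups compared, slide and replicate number as blocks, and each array left out in turn. Replicate numbers were checked for pairing by correlating same-numbered deviations between groups and were not taken to pair the samples. Intergenic features were tested apart and enter no list.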

Results

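Transcript levels were measured on 27 arrays, 3 for each of 9 groups: the strains AE104, De4 and De4zupT, each untreated, with Zn or with EDTA, which binds divalent metals. Between 75.9% of probes (De4 with Zn, replicate 1) and 91.5% (untreated AE104, replicate 1) were well above background, the median processed signal lay between 55.8 and 98.0, and 5240 of the 6263 genes tested were well above background on all 27 arrays. Correlations across genes between replicates were 0.987 to 0.995, and between arrays of different groups 0.824 to 0.993. The number of arrays limits the precision. The levels below are log2 processed signals relative to each array's 75th percentile, with the SD over 3 arrays.

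The genes that the mutants lack were examined first. The zinc-exporting P-type ATPase gene zntA stood at −2.40 ± 0.09 in untreated AE104 and at 2.12 ± 0.08 with Zn, and cadA, which encodes a related ATPase, went from −0.43 ± 0.39 to 4.13 ± 0.15; both rose with Zn, 23.0-fold and 23.6-fold. The genes of the cation diffusion facilitators dmeF and fieF were expressed in AE104 at 0.73 ± 0.11 and −0.65, and their Zn differences, 0.51 and 0.10, did not pass the test (adjusted p = 0.0608 and 0.817, limma). In untreated De4, cadA was at least 25.1-fold lower than in AE104, dmeF at least 55.7-fold and fieF at least 21.5-fold, and in De4zupT at least 22.1-fold, 49.1-fold and 19.0-fold. The zntA signal was lower by log2 −2.62 in De4, where 3 of 3 untreated arrays were still well above background, and by −3.23 in De4zupT, where 1 was. With signals below the lowest well above background raised to it, these were −2.40 and −2.48. The zinc importer gene zupT was at −1.44 in AE104 and −1.51 in De4, and at least 10.9-fold and 10.4-fold lower in De4zupT; no treatment changed it, with Zn differences of −0.02 in AE104 and 0.09 in De4. All 10 of these targeted falls were called. With slide as a block 8 were, since the zntA differences became −2.28 and −2.38 (adjusted p = 0.0666 and 0.139).

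**Figure D1:**
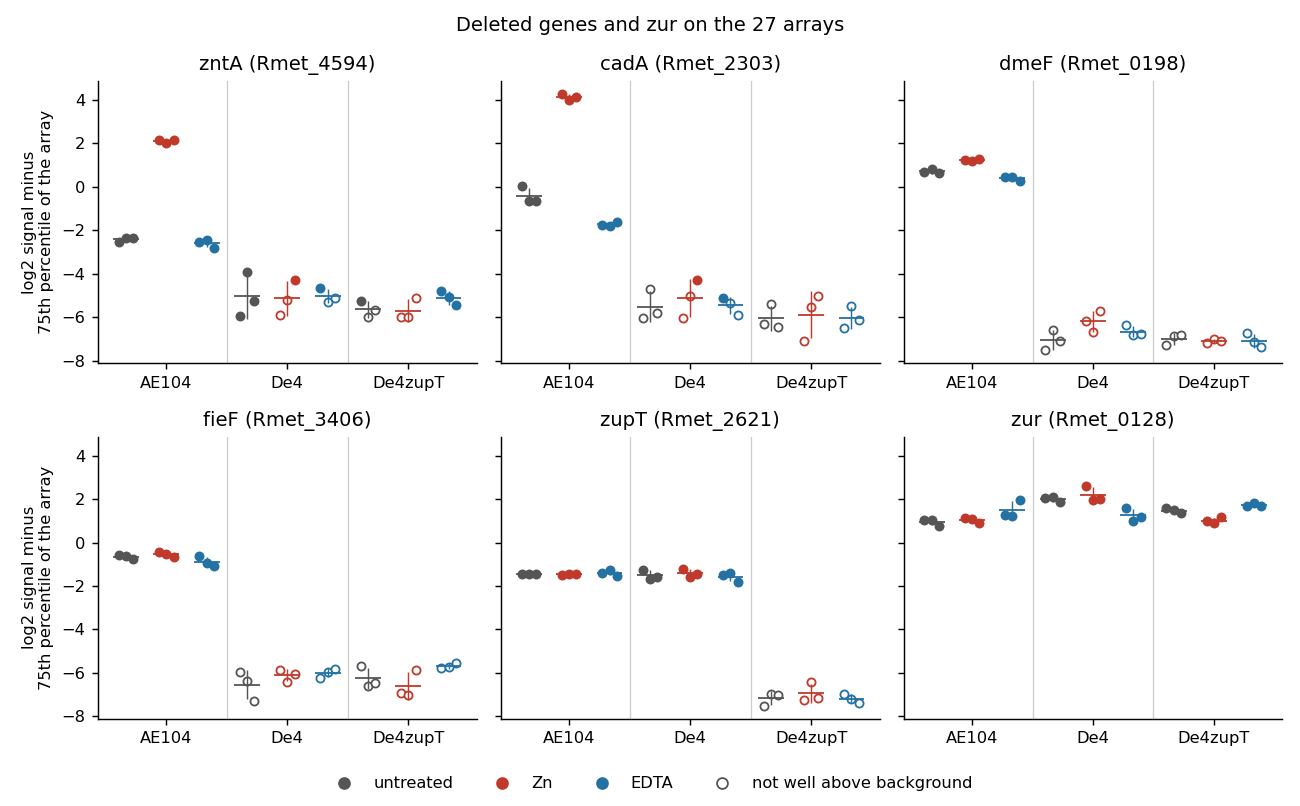
Level of the 6 genes fixed beforehand on every array (vertical axis, log2 processed signal relative to the array's 75th percentile) by strain and treatment; points are arrays, open where the gene was not well above background, horizontal bars are means and vertical lines ± SD over 3 arrays. The zntA signal in AE104 lies near −2.40 untreated and 2.12 with Zn, and zupT is not well above background in De4zupT.

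The plasmids pMOL28 and pMOL30, which AE104 is known to lack, are represented by 353 intergenic probes. On average 21.8 ± 4.1% of these were well above background over the 27 arrays (21.8% in AE104, 21.7% in De4, 21.9% in De4zupT), against 0.24% of negative control spots and 89.5% of the chromosome's intergenic probes. By another mark, the 95th percentile of the negative controls, 58.9 ± 11.5% of the plasmid probes and 96.4% of those of the chromosome lay above it, so the share depends on the mark. Their median levels were −6.34 and −6.16, against −1.55 for intergenic probes of the chromosome and −2.75 for those of the second chromosome.

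Zn in AE104 asks how the parent strain responds to an excess of zinc. Besides zntA and cadA, genes of phosphate uptake rose: pstC by log2 3.72 (SE 0.22) and pstA by 3.71 (SE 0.26), of 4 phosphate genes measured. Flagellar genes fell, 12 of 20, among them flgD (−1.89) and flgB (−1.81), which encode parts of the rod and hook, flhB (−1.65) of the export apparatus, and fliG (−1.61) of the motor switch. Of 47 ribosomal protein genes 11 fell, such as rplM (−1.43) and rpsO (−1.20). Of 10 chaperone and protease genes 2 rose, hslU (1.28) and hscA (1.22), and gltD, a subunit of glutamate synthase, fell by 1.18. The tags with the largest changes were Rmet_3620 (7.63, SE 0.17) and Rmet_4026 (5.17, SE 0.10) upward, and Rmet_3144 (−4.57, SE 0.14) and Rmet_4564 (−4.32, SE 0.18) downward. In all, 221 genes were higher and 293 lower (adjusted p under 0.05 and log2 of at least 1), and at an adjusted p under 0.05 alone 1395 and 1265. The list medians were −0.78 for ribosomal proteins (camera adjusted p = 4.3e-13; adjusted p = 0.336 with an estimated correlation), −1.22 for flagella (1.8e-10; adjusted p = 0.250 estimated), 0.42 for chaperones (0.0159; adjusted p = 0.250 estimated) and 0.44 for 6 histidine synthesis genes, of which none was called (0.0346; adjusted p = 0.242 estimated). Adjusted over the list alone, 11 ribosomal, 12 flagellar and 2 chaperone genes were called, as over all genes. With the authors' value table the split of calls was 389 higher and 139 lower, and the median of all genes 0.37 in place of 0.04.

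In De4, Zn raised chaperone and protease genes: 6 of 10 rose, with hslU, the ATPase of a protease, at log2 3.91 (SE 0.19), the adaptor gene clpS at 2.52, and the chaperonin genes groES at 2.07 and groEL at 1.82. Flagellar genes fell in 17 of 20 cases, such as fliG (−3.90), flgB (−3.57) and flgE (−3.46). Of the 47 ribosomal protein genes 17 fell, among them rpsO (−1.35) and rpsI (−1.25). The phosphate genes pstA (1.81) and pstC (1.63), hscA (1.15) and hscB (1.43) of iron-sulfur cluster assembly and kgd (1.40) rose, while gltD (−2.34), secG (−1.43), dcd (−1.41), lpxD (−1.47) and fabZ (−1.19) fell. Rmet_1768 rose by 8.63 (SE 0.13) and Rmet_6174 at least 113-fold; Rmet_4565 fell by 4.57 (SE 1.34, with an SD of 2.62 among the untreated arrays; −3.93, −6.08 and −3.70 without untreated replicate 1, 2 or 3) and Rmet_3144 by 4.54. There were 367 higher and 552 lower genes. The list tests gave adjusted p = 2.6e-12 for flagella (median −2.65, and −1.05 with normexp; adjusted p = 0.181 with an estimated correlation), 2.5e-10 for ribosomal proteins (−0.88; adjusted p = 0.308 estimated), 6.8e-05 for chaperones (1.29; adjusted p = 0.0912 estimated), 0.0244 for translation factors (−0.43, 2 of 10 lower), 0.0313 for aminoacyl-tRNA synthetases (−0.36, 0 of 18 called) and 0.0327 for cell wall and lipopolysaccharide synthesis (−0.26, 2 of 14 lower), with adjusted p = 0.308 estimated for the last 3. Adjusted over the list alone the counts for these lists were the same. The 7 genes of the TCA cycle had a median of −0.30 and a mean of 0.09, with 2 higher.

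In De4zupT, Zn changed genes of the same 3 lists. Chaperone genes rose in 6 of 10 cases, with hslU at log2 3.56, clpS at 2.09 and groEL at 1.44. Flagellar genes fell in 15 of 20 cases, led by flgB (−3.10) and flgD (−3.03), with fliG at least 7.67-fold lower. Ribosomal protein genes fell in 17 of 47 cases, such as rpsS (−1.29) and rpsC (−1.24). The genes pstA (1.75), pstC (1.59), hscB (1.53), kgd (1.38), hscA (1.27), trpD (1.22) and cysM (1.19) rose, and gltD (−2.73), secG (−1.36) and dcd (−1.30) fell. Rmet_1768 rose by 8.21 and Rmet_6174 at least 117-fold, and Rmet_3144 fell by 4.76 and Rmet_4565 by 4.04 (SE 1.34; not called without untreated replicate 1 or 3, and −5.25 and −3.35 without untreated replicate 2 or 3). The total was 323 higher and 437 lower genes, and 52.9% higher with the authors' value table against 42.5% here. Camera (limma) gave adjusted p = 5.1e-12 for ribosomal proteins (median −0.92; adjusted p = 0.388 estimated), 3.3e-11 for flagella (−1.94, and −0.85 with normexp; adjusted p = 0.246 estimated) and 3.8e-05 for chaperones (1.33; adjusted p = 0.0751 estimated). Adjusted over the list alone the counts were again 17, 15 and 6.

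**Figure D2:**
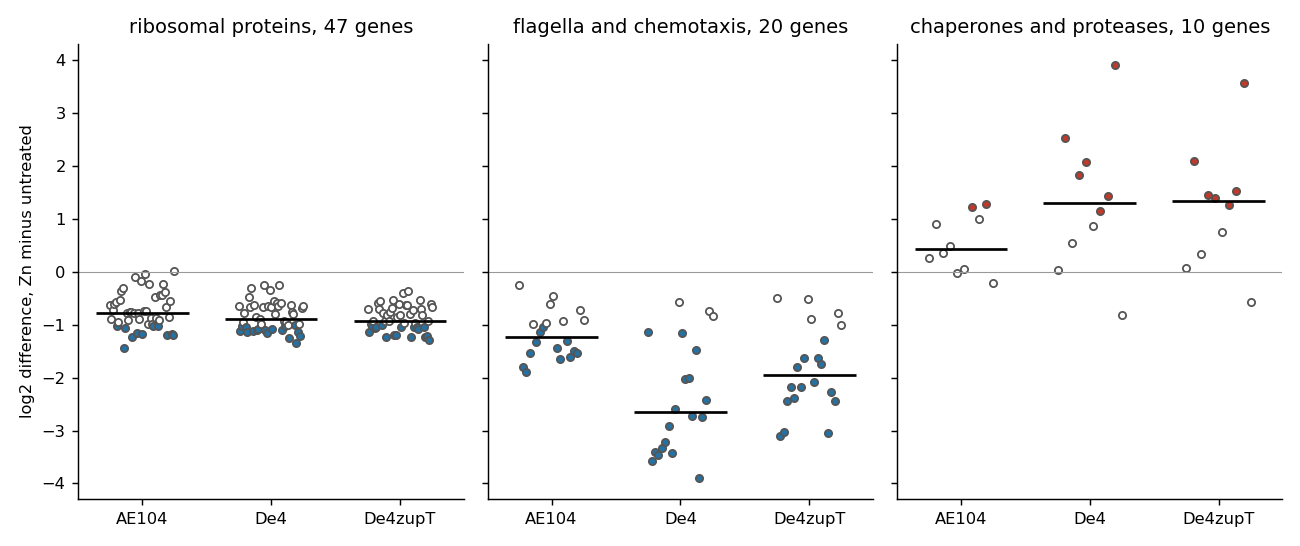
Zn difference (vertical axis, log2, Zn minus untreated) of each member of 3 lists in AE104, De4 and De4zupT; red points were called higher, blue lower, open points were not called, and lines are medians. The flagellar medians are −1.22, −2.65 and −1.94, and the chaperone medians 0.42, 1.29 and 1.33.

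The Zn responses of the strains shared many genes. In AE104 and De4 the same 126 genes rose (13.0 by chance, adjusted p = 5.4e-103, one-sided exact hypergeometric test) and 204 fell (25.8 by chance, 3.3e-158), while 9 genes that fell in AE104 rose in De4. AE104 and De4zupT shared 112 rises and 205 falls (11.4 and 20.4 by chance), and the mutants 287 and 384 (18.9 and 38.5 by chance). In all 3 strains 108 genes rose and 197 fell. Across genes, which are not independent replicates, the Zn differences correlated at 0.58 for AE104 and De4, 0.60 for AE104 and De4zupT and 0.93 for the mutants.

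The difference of the Zn effects tests which responses differed between De4 and AE104. The chaperone and protease genes hslU (2.64), groES (2.09), clpS (1.61) and groEL (1.33) responded more strongly in De4, as did trpD (1.46) and kgd (1.08), and the chaperone list had a median difference of log2 0.62 (0.49 with normexp, 0.23 with the value table). Flagellar genes responded with a larger fall, 11 of 20, such as flgI (−2.37), flgF (−2.34) and fliG (−2.29), although the list's median of −1.38 was −0.085 with normexp, and the phosphate genes pstC (−2.09) and pstA (−1.90) with a smaller rise. Untreated De4 stood higher than AE104 for pstC and pstA and lower for groES, as given below. Part of these 3 differences can thus lie in the untreated levels, which are compared between slides. Rmet_1768 (8.86) and Rmet_48660 (7.31) led the higher tags. The deleted genes zntA and cadA were among the lower calls, with signals in De4 well above background on only 1 of 3 Zn arrays each, so no size is given. In total 275 genes were higher and 229 lower; the split was 171 and 74 with normexp, 322 and 174 with median scaling and 131 and 402 with the value table. Adjusted p was 1.2e-05 for flagella (camera; adjusted p = 0.527 with an estimated correlation), 0.00403 for chaperones (adjusted p = 0.322 estimated) and 0.0167 for cell wall synthesis (−0.43, 0 of 14 called; adjusted p = 0.322 estimated). Adjusted over the list alone, 11 flagellar and 4 chaperone genes were called.

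Between De4zupT and De4 the Zn effect differed for 12 genes. Of these 6 were the tags Rmet_1098, Rmet_1099 and the next 4 in number, a run chosen after its values were seen, which fell in De4zupT (log2 −3.57 to −2.44) and were not called in De4. Rmet_1103 (−3.87) and Rmet_1101 (−3.76) had the largest negative differences, and Rmet_2299 (1.68, not called without De4zupT Zn replicate 1) was among the 2 positive ones. Of 19 tags that neighbour zupT and zur in number 2 were lower (median −0.16, with a sign that turns to 0.02 with the value table; camera adjusted p = 0.00263, and adjusted p = 0.0167 with an estimated correlation). Flagellar genes had a median difference of 0.48 (0.12 with normexp, 0.26 with the value table), with camera adjusted p = 3.9e-08 (adjusted p = 0.270 estimated). Of these 0 of 20 were called, and 4 were higher when adjusted over the list alone. Synthetases (median 0.18, 0.00384; adjusted p = 0.270 estimated) and TCA genes (0.18, 0.0353; adjusted p = 0.288 estimated) had 0 called. Without De4 Zn replicate 1 or De4 untreated replicate 2, 24 and 20 genes were called in place of 12.

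EDTA changed few genes. In AE104 no gene with a symbol was called; Rmet_0124, which stands 4 tag numbers before zur, rose by log2 2.04 (SE 0.18, adjusted p = 1.3e-06) and Rmet_6253 by 2.31 (SE 0.53), while Rmet_4596 (−3.73, SE 0.47), Rmet_6002 (−2.74) and cadA (−1.30, SE 0.46, adjusted p = 0.045) fell. Ribosomal protein genes had a median of 0.62 with 0 of 47 called, RNA polymerase and elongation genes 0.49 with 0 of 12, and histidine synthesis genes 0.46 with 0 of 6, although all 6 had an adjusted p under 0.05. In all 35 genes were higher and 11 lower (21 and 17 with median scaling, 112 and 6 with the value table), and at an adjusted p under 0.05 alone 1004 and 489. Camera gave adjusted p = 5.7e-09 for ribosomal proteins, 3.2e-05 for RNA polymerase, 0.0335 for TCA genes (median 0.44) and 0.0164 for translation factors (0.33). With an estimated correlation these lists had, in that order, adjusted p = 0.341, 0.290, 0.290 and 0.290. The translation factor median was 0.22 with median scaling and 0.13 with the value table. For the histidine list camera gave adjusted p = 0.00127 (adjusted p = 0.0230 estimated, and adjusted p = 0.0869 estimated with slide as a block). With slide as a block 70 genes were called, 28 of them among the 46, including Rmet_0124 (1.94) but not Rmet_6253 (1.45) or cadA (−1.38, adjusted p = 0.225), which was also lost without any 1 of the 6 arrays; Rmet_4596 was −2.72 and −4.39, and Rmet_6002 −1.86 and −3.40, without untreated replicate 2 or 3, and Rmet_6253 was 1.55 without EDTA replicate 3. Within slide 1 the median change of the 46 genes was 1.24 against 1.30, a value from 1 EDTA array that also entered the calls, so it does not test the slides.

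In De4 with EDTA, Rmet_0124 was the only gene that rose (log2 1.26, adjusted p = 0.000883), and Rmet_4597 (−3.30) and Rmet_6002 (−3.02) led the 5 that fell. The others were Rmet_2997 (−2.19), Rmet_2998 and Rmet_6170, printed because the count is small. No ribosomal or flagellar gene of the lists was called. Neither was zntA, cadA, dmeF or fieF, but De4 is known to lack these, so no call could be looked for. Other efflux genes cannot be told among the tags, which have no names. The call of ribosomal proteins (median 0.12, camera adjusted p = 0.0150) was lost with an estimated correlation (adjusted p = 0.913) and turned with slide as a block (−0.22, 2.7e-06; adjusted p = 0.486 estimated), as did nucleotide synthesis, not called before (0.00489; adjusted p = 0.245 estimated). With that block 2 genes were called, of which Rmet_2997 was in the first list, Rmet_4597 and Rmet_6002 stood at −3.35 and −3.04 with wider errors (adjusted p = 0.0996 and 0.177), and Rmet_0124 at 0.91 (adjusted p = 0.371); without De4 EDTA replicate 1, 14 genes were called, and with normexp 0 were higher and 3 lower.

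In De4zupT with EDTA 36 genes were higher and 8 lower, and 13 of these 44 had a dim group. Rmet_4597 (log2 −3.61) and Rmet_6002 (−3.20) led the falls, and Rmet_0124 rose by 1.47. Rmet_6319 rose by 2.47 (not called without untreated replicate 2), from an untreated mean of −5.29 ± 0.99. The lowest signals well above background on those 3 untreated arrays were −5.27, −4.67 and −4.73, so the size is uncertain. Rmet_6166, dim when untreated, rose at least 2.22-fold (not called without untreated replicate 1, EDTA replicate 1 or EDTA replicate 2). Another tag dim when untreated had a larger bound, at least 3.17-fold. No list passed its test in the fit without slides, and 0 symbols were called. Rmet_0124 was thus higher, and Rmet_4597 and Rmet_6002 lower, with EDTA in each of the 3 strains; between De4 and De4zupT 1 rise and 5 falls were shared (0.00575 and 0.00639 by chance, adjusted p = 0.00627 and 1.2e-15, one-sided exact hypergeometric test). The EDTA arrays of De4zupT lay on another slide than its untreated arrays, with no array pair on 1 slide. With slide as a block 34 genes were called, of which 1 was among the 44, namely Rmet_0124 (2.18); Rmet_4597 (−3.49, SE 1.18, adjusted p = 0.219) and Rmet_6002 (−3.13, SE 1.19, adjusted p = 0.272) kept their size, Rmet_6319 was 0.82 and Rmet_6166 turned to −0.48. The block also changed the lists: ribosomal proteins went from a median of 0.0091 to 0.53 (camera adjusted p = 6.0e-11; adjusted p = 0.391 estimated), and RNA polymerase (0.34, 0.0136; adjusted p = 0.391 estimated), flagella (0.42, 0.0366; adjusted p = 0.572 estimated) and nitrogen assimilation (−0.49, 0.0366; adjusted p = 0.391 estimated) were called. Without EDTA replicate 2, EDTA replicate 1 or untreated replicate 1, 15, 17 and 22 genes were called, and the split was 1 and 4 with normexp and 8 and 5 with the value table.

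**Figure D3:**
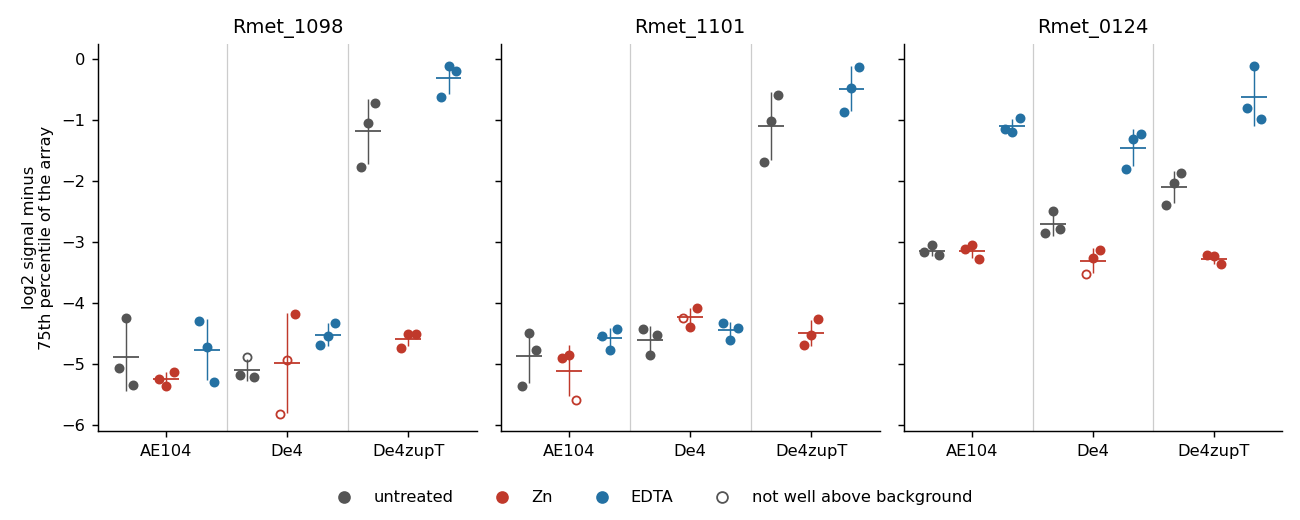
Level (vertical axis, log2 processed signal relative to the array's 75th percentile) of Rmet_1098, Rmet_1101 and Rmet_0124 on every array by strain and treatment; points are arrays. The first 2 are raised in untreated De4zupT, and Rmet_0124 with EDTA in all 3 strains.

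The EDTA effect differed between De4 and AE104 for 47 genes, 6 higher and 41 lower in De4 (19 and 31 with median scaling). The zur gene, which encodes the zinc uptake regulator, was among the lower ones (log2 −1.28, adjusted p = 0.00582), with no call when slide was a block (−0.71, adjusted p = 0.254). The histidine synthesis list had a median of −0.44 (camera adjusted p = 0.00125, adjusted p = 0.0229 with an estimated correlation), with 0 of 6 called (adjusted p = 0.00204, and adjusted p = 0.0952 estimated, with slide as a block). Rmet_6253 (−3.60, and −2.85 without AE104 EDTA replicate 3) and Rmet_5419 (−2.31) had the largest negative differences, and 0 of these 2 were called with slide as a block. Ribosomal protein genes (median −0.49, 6.9e-06), TCA genes (−0.40, 0.00421), RNA polymerase genes (−0.38, 0.000276), translation factors (−0.32, 0.0226) and amino acid synthesis (−0.35, 0.0447) lost the call with an estimated correlation (adjusted p = 0.502 for the first and 0.345 for the others). The block left 39 calls, 11 of them shared, and without De4 EDTA replicate 1 there were 97. Between De4zupT and De4 15 genes differed, 14 higher and 1 lower (511 of the 6263 genes had an unadjusted p under 0.05 in limma), but only 2 and 0 with normexp and 0 and 0 with the value table (337 genes at an unadjusted p under 0.05, limma). Rmet_2151 (2.26) had the largest difference among tags that were dim in none of the 4 groups; the 1 lower tag, Rmet_1296, was dim in all 4 and is given no size. With slide as a block 15 were called, 0 of them shared, and Rmet_2151, which was also not called without De4 untreated replicate 2, turned to −0.59. No list was called without the block, and 6 were with it: ribosomal proteins (median from −0.13 to 0.78, camera adjusted p = 7.1e-12; adjusted p = 0.314 estimated), RNA polymerase (0.0114; adjusted p = 0.411 estimated), nucleotide synthesis (0.0130; adjusted p = 0.314 estimated), synthetases (0.0176; adjusted p = 0.314 estimated), TCA genes (0.0265; adjusted p = 0.314 estimated) and flagella (0.0428; adjusted p = 0.604 estimated). Without De4 EDTA replicate 1 there were 56 calls, and 4 to 8 without De4 EDTA replicate 2 or 3, De4 untreated replicate 2, De4zupT untreated replicate 1 or De4zupT EDTA replicate 1 or 2.

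Untreated De4 against AE104 asks how the strains differed without added metal. Apart from the deleted genes, rbcL (log2 −3.95), the large subunit of the carbon-fixing enzyme Rubisco, and pgk__2 (−4.66), named as a copy of the phosphoglycerate kinase gene, were lower. Of 47 ribosomal protein genes 15 were higher, such as rplE (1.28), rpsN (1.28) and rplD (1.23), as were pstC (1.37), pstA (1.14, not called without De4 replicate 2), the carbamoyl phosphate synthase gene carB1 (1.31), and rbfA (1.09), while groES was lower (−1.08, not called without AE104 replicate 1). Rmet_3835 was higher by 8.32 (SE 0.08) and Rmet_3834 by 7.19, and Rmet_1535 was at least 4386-fold and Rmet_1526 at least 2887-fold lower. The zur gene was higher by 1.04 (adjusted p = 7.7e-05; not called without AE104 replicate 3 or De4 replicate 2). In all 259 genes were higher and 229 lower, with a median of all genes of 0.14 that median scaling took to −0.00; the split was 87 and 133 with normexp, 173 and 265 with median scaling and 344 and 189 with the value table. Camera gave adjusted p = 6.6e-07 for ribosomal proteins (median 0.81; adjusted p = 0.784 with an estimated correlation; 15 called when adjusted over the list alone) and 0.00106 for RNA polymerase genes (0.63, 0 of 12 called; adjusted p = 0.742 estimated). No untreated array of the 2 strains shares a slide. With slide as a block 485 genes were called, 333 of the 488 among them, with zur at 0.30, pstC at 0.96 and groES at −0.86 not called and the ribosomal median at 0.88; on slide 3, where 1 EDTA array of each strain lies, 454 of the 488 kept their direction (93.0%) with a median of 1.40 against 1.66, while the ribosomal median was −0.00, with rplE at 0.26, between EDTA arrays, on which AE104 itself stood higher than untreated by 0.62.

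De4zupT against AE104 had nearly the same leading tags. Rmet_3835 was higher by log2 8.29 and Rmet_3834 by 7.22, and Rmet_1535 was at least 3867-fold and Rmet_1526 at least 2546-fold lower. Ribosomal protein genes were higher in 8 of 47 cases, and greB (1.09) of transcription was higher. The flagellar genes flgD (−1.16) and fliP (−1.02, not called without AE104 replicate 2 or 3 or De4zupT replicate 2) were lower, of 20. Of the 19 neighbours of zupT and zur 5 were higher. The total was 252 higher and 254 lower (85 and 130 with normexp, 166 and 290 with median scaling). Camera gave adjusted p = 1.6e-06 for ribosomal proteins (median 0.74; adjusted p = 0.601 estimated), 4.4e-07 for flagella (−0.70; adjusted p = 0.409 estimated), 0.000518 for RNA polymerase genes (0.67; adjusted p = 0.493 estimated), 0.0476 for translation factors (0.34; adjusted p = 0.493 estimated), and 0.0350 for the neighbours (0.78) and for histidine synthesis (0.49), both with adjusted p = 0.136 estimated. Adjusted over the list alone 8 ribosomal, 2 flagellar and 5 neighbouring genes were called. Slide as a block gave 525 calls, 295 of the 506 among them; the ribosomal list was not called (0.33, adjusted p = 0.451), flgD and fliP (0.01) were lost, and on slide 2 (3 EDTA arrays against 1) 495 of the 506 kept their direction (97.8%), with a ribosomal median of 0.23 and a flagellar one of −0.27.

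The mutants shared 183 genes higher than in AE104 (10.4 by chance for independent lists) and 212 lower (9.29 by chance). Both comparisons use the same AE104 arrays, and simulated unchanged groups against those arrays shared 0 calls in 20 simulations. Across genes the differences correlated at 0.962, against 0.503 simulated, with a covariance of 1.11 against 0.0175. The shared controls, too few to split, can hold part of the excess. All untreated AE104 arrays also lay on slide 1, which held no mutant array. A shift of that slide would enter both differences alike, and the simulated unchanged groups would not show it. The comparisons within a slide, given above, use EDTA arrays only. The genes lower in both mutants lay close together in tag number. With runs defined, after the values were seen, as at least 10 such genes with gaps of at most 10, 4 runs held 168 of the 212: Rmet_1237 to Rmet_1338, Rmet_1491 to Rmet_1547, Rmet_3013 to Rmet_3045, and Rmet_4594 to Rmet_4618, which starts at zntA. In the second 52 of 54 tested genes were lower in both mutants, in the fourth 15 of 25, with 7 higher in a mutant. The runs had 206 tested genes and held 73.8% of the genes lower in De4 and 69.7% of those lower in De4zupT. Taking tag numbers for gene order is an assumption, as no genome was used here.

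**Figure D4:**
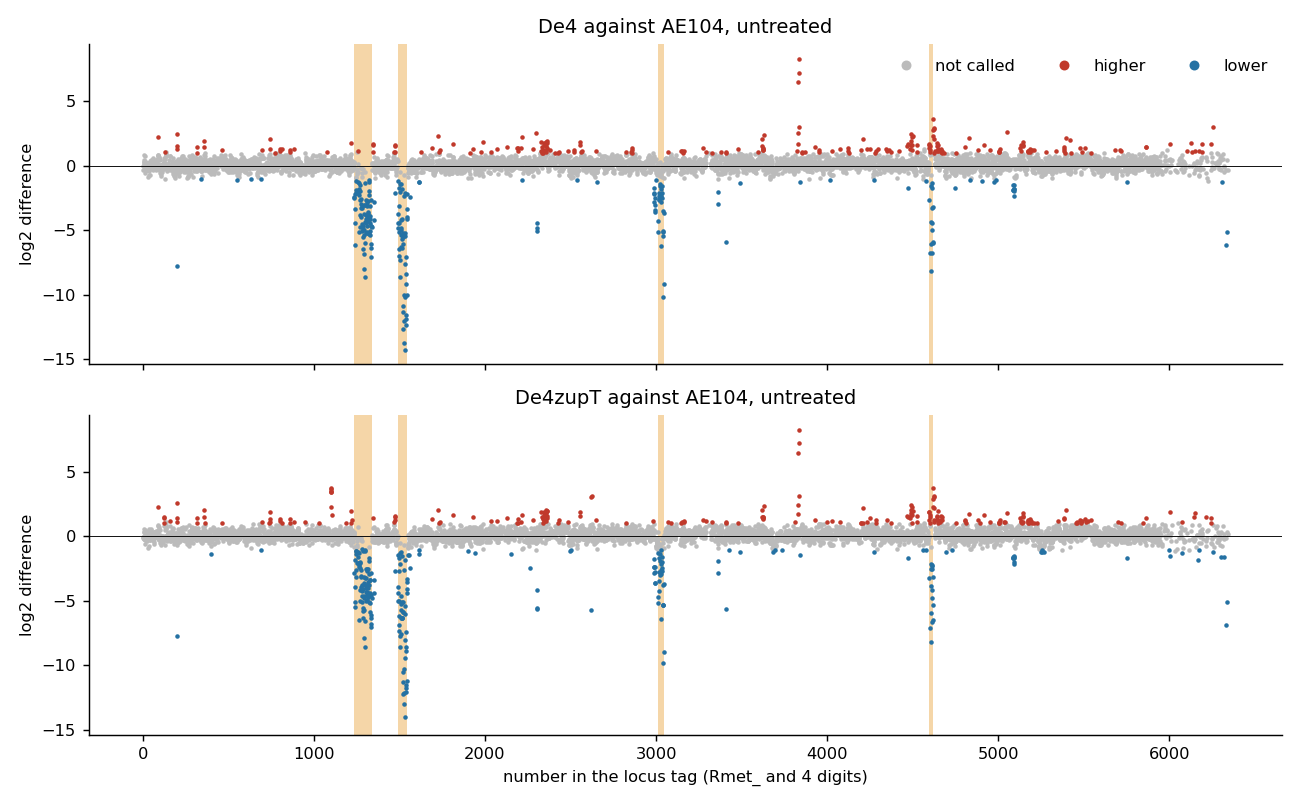
Difference between each untreated mutant and AE104 (vertical axis, log2) by 4-digit tag number (horizontal axis), with a panel per mutant; red points were called higher, blue lower, grey not called, and shading marks the 4 runs. The 168 genes of the runs that are lower in both mutants form blocks, with Rmet_1535 and Rmet_1526 at the lowest values.

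De4zupT against De4 asks what the added deletion of zupT changes, between strains whose untreated arrays lay on different slides. With zupT included, 31 genes differed, 12 higher and 19 lower. The tags 1 and 2 numbers after zupT were higher by log2 2.94 and 3.09, and the 6 tags from Rmet_1098 (3.92, SE 0.33) to Rmet_1103, with Rmet_1101 at 3.51, were all higher, by 2.11 or more. Rmet_2263 was lower (−2.68). Flagellar genes had a median of −0.58 with 0 of 20 called. Camera gave adjusted p = 9.2e-12 for the neighbours of zupT and zur (median 0.27, 4 of 19 higher, also when adjusted over the list alone; adjusted p = 6.3e-06 with an estimated correlation), 3.7e-15 for flagella (adjusted p = 0.0997 estimated) and 0.0149 for amino acid synthesis (0.16, 0 of 13 called; adjusted p = 0.149 estimated). No symbol was called. The split was 8 and 5 with normexp and 17 and 15 with quantile normalization, and 18 genes were called without De4 untreated replicate 2. With slide as a block 68 genes were called, 16 of the 31 among them, with 5 of the 6 tags of the run (1.83 to 3.70) and medians of 0.30 for the neighbours (adjusted p = 1.9e-06; adjusted p = 0.000924 estimated) and −0.52 for flagella (1.9e-06; adjusted p = 0.325 estimated). Amino acid synthesis lost its call (adjusted p = 0.106). Lists not called before were called with it: ribosomal proteins (median from −0.06 to −0.58, 2.3e-12; adjusted p = 0.325 estimated), RNA polymerase (0.05 to −0.18, 0.0304; adjusted p = 0.460 estimated), nucleotide synthesis (0.03 to −0.14, 0.0152; adjusted p = 0.325 estimated) and DNA replication (−0.06 to −0.10, 0.00892; adjusted p = 0.0966 estimated). Slide and strain are thus hard to part here, as no slide holds arrays of both strains with the same treatment.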

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

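The tests of slides, of runs, and of scaling and DNA loss within the runs for De4 against AE104, of the loss of the efflux genes for flagella and EDTA, and of regroupings after the mean of each strain was taken out were chosen only after the result was seen.

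The response to Zn or EDTA differed between strains by a test of the difference itself in 4 cases, and each was set against 100 reassignments of strain among arrays of the same treatment, the real one included. For the Zn effect of De4 against AE104, 504 genes were called; 9 of the 100 reassignments gave as many, with up to 1019 in another. For De4zupT against De4 with Zn it was 12 genes, 8 reassignments and up to 137, and for De4 against AE104 with EDTA 47 genes, 14 reassignments and up to 1236, so chance is not excluded for these 3 by this test. For De4zupT against De4 with EDTA 15 genes were called and 4 reassignments gave as many (up to 32 in another), a share under 0.05 for that fit. The count itself rests on the fit: with slide as a block none of those 15 was called, normexp gave 2 calls and the value table gave 0 (337 genes at an unadjusted p under 0.05, limma), and without 1 array 4 to 56. Reassignments that call several times the real count point to a structure of the samples, here the difference between the strains themselves, which enters the contrast when strains are mixed. With each strain's mean subtracted beforehand, 1, 2, 1 and 1 of the 100 gave as many genes, with up to 219, 21, 22 and 14 in another. By this later test each share was under 0.05. The reassignments mix arrays of different slides, so they cannot set strain apart from slide, which matters for the EDTA differences.

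The 9 comparisons of groups allow only 10 splits of 6 arrays, too few for a share under 0.05. The real count and the highest of the other splits were 514 and 5 for Zn in AE104, 919 and 28 for Zn in De4, 760 and 0 for Zn in De4zupT, 46 and 2 for EDTA in AE104, 44 and 0 for EDTA in De4zupT, 488 and 1 for De4 against AE104, 506 and 0 for De4zupT against AE104, and 31 and 0 for De4zupT against De4, where 1 split, the real one, gave as many. For EDTA in De4 they were 6 and 8, and 2 splits gave as many; the other one grouped EDTA replicate 1 with untreated replicates 1 and 3, all from slide 3, and with slide as a block 2 genes were called.

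Genes lower in De4 than in AE104 lay in runs of tag numbers, Rmet_1491 to Rmet_1547 foremost, where the median level was 0.77 in AE104 and −5.19 in De4. Against a difference between slides as the whole cause, the called genes changed on slide 3 by 0.846 of their change in the comparison, a value that rests on 1 EDTA array per strain. The ratio was 0.964 in the runs, where 100% kept their direction. For the 312 called genes outside the runs it was 0.730, with 89.1% in the same direction, so the argument is weaker for these. With slide as a block 333 of 488 calls were kept. That fit links the untreated strains only through 1 AE104 EDTA array on slide 1 and 1 on slide 3. Scaling is argued against for the runs, where at least 58.6% of the 169 genes lower in De4 stayed lower under each of 4 scalings and the median difference was at least 1.27 in size. With normexp as few as 45.1% of all calls were kept, and 37.2% of the 312 outside the runs. The median signed change of those 312 was 0.90 with normexp and 1.19 to 1.25 under the other scalings, against 1.28. Scaling thus does not account for most of their size, but which of them pass the threshold depends on it. A loss of the whole run that starts at zntA is argued against by 7 of its 25 genes, which were higher in a mutant. For the first 3 runs, 34.1% of the genes bright on all 9 AE104 arrays were well above background on none of the 18 mutant arrays. Probes for the plasmids, which AE104 is known to lack, were themselves well above background in 21.8% of cases. Signal at the level of the plasmid probes thus does not tell against a loss. On average, genes lower in both mutants in the first 3 runs were well above background on 3.97, 7.42 and 4.48 of 18 mutant arrays. The run from Rmet_1491 thus exceeded the plasmid share. Its medians, −5.19 in De4 and −5.95 in De4zupT, lay above the plasmid medians of −6.34 and −6.16. The plasmid comparison does not cover that run, for which a loss of the whole stays undecided. Over all 4 runs 15 genes were called with Zn or EDTA in De4 and 11 in De4zupT, some of them, such as Rmet_1281, dim when untreated. A loss of DNA and a lack of transcription cannot be told apart, as no DNA was measured. An effect of the missing efflux genes stays open, as untested.

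The fall of flagellar genes with Zn was larger in De4 than in AE104, with a median difference of −1.38 and 11 of 20 genes called. The dim array De4 with Zn, replicate 1, is argued against as the cause, as the median was −1.43 without it. Scaling or background correction stays open: the median was −0.085 with normexp, while it was −1.49, −1.30 and −0.95 with quantile normalization, median scaling and the value table. The loss of the efflux genes stays open: De4zupT, which shares it, had a median difference from AE104 of −0.72 (5 of 20 called, camera adjusted p = 0.0103, adjusted p = 0.843 with an estimated correlation). Both differences use the same 6 AE104 arrays. If the whole De4 difference were error of the arrays, the shared ones would give −0.70 (a share of 0.506), but that assumption was not tested. The strains also started from different levels. Untreated, the median difference of the list from AE104 was −0.13 in De4 and −0.70 in De4zupT, between slides. The smaller difference of the Zn effect in De4zupT thus goes with a lower start and need not mean a higher level with Zn.

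EDTA changed 46 genes in AE104 and 6 in De4. A difference between slides stays open as the cause of that gap. With slide as a block the ratio of calls was 35 (70 against 2). In each strain, however, that fit compares 1 EDTA array with the untreated arrays of its slide. In De4, Rmet_4597 and Rmet_6002 kept their size in it (−3.35 and −3.04, against −3.30 and −3.02) and lost their calls through wider errors. A single AE104 EDTA array is argued against as the cause, since the lowest ratio without 1 of them was 7.17 (43 against 6, without replicate 3). The missing efflux genes stay open: De4zupT, which lacks them too, had 44 calls (34 with slide as a block, 1 of them shared), but its EDTA and untreated arrays share no slide.

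Intergenic features, which enter none of the comparisons of genes, gave calls too: 217 of 3059 with Zn in AE104, 356 with Zn in De4, 309 with Zn in De4zupT and 314 for De4 against AE104.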

How the results depend on the processing

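Intergenic features in the fit, the comparisons within a slide, the flagellar difference of De4zupT and slide as a block in set tests, with a preset and an estimated correlation, were chosen after seeing the data. Where no cause is given, the cause was not tested. Of the 714 results for named genes, 12936 values under alternatives stayed on their side of the threshold, 75 became stronger and 259 weaker and 4 reversed; for the 208 list results it was 1643, 100, 119 and 10. Counts in the next paragraph differ by over 1.5 times from those in the report, and counts under the other alternatives, single arrays left out aside, were within that.

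With normexp, Zn called 294 (AE104), 520 (De4) and 423 (De4zupT), EDTA 20, 3 and 5, the strains 220, 215 and 13 (De4, then De4zupT, against AE104, then De4zupT against De4), the differences of effects 245 (Zn, De4 minus AE104), 28 and 2 (EDTA), and overlaps were 189, 174 and 379 for Zn and 3 for EDTA in the mutants. Without a fold minimum, which by construction adds genes, the counts were 2660, 3261 and 2849, 1493, 14 and 118, 2866, 2698 and 109, 1989 and 410, and the overlaps 1631, 1609 and 2509 for Zn and 6, 42 and 10 for EDTA. With the value table EDTA called 118 in AE104 and 13 in De4zupT, and its differences 86 and 0 (337 genes at an unadjusted p under 0.05, limma). Genes well above background on all 27 arrays, fewer by construction, gave 21 for EDTA in De4zupT, 261, 268 and 18 for the strains and 4 for Zn in De4zupT minus De4. Slide as a block gave 70 and 2 for EDTA in AE104 and De4 and 68 for De4zupT against De4; only the groups compared gave 6 for Zn in De4zupT minus De4 and 16 and 4 for the EDTA differences. Quantile and median scaling each gave 5 for the EDTA overlap of AE104 and De4. Plasmid probes over the 95th percentile of negative controls were 58.9%. List calls went from 43 to 4 with an estimated correlation, 2 with that and slide as a block, and 94 with fry, which tests another question.

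Lists are named here where the direction that camera gave reversed, with its adjusted p. With slide as a block these were ribosomal proteins with EDTA in De4 (2.7e-06), in De4zupT (6.0e-11, with a median that kept its sign) and in their difference (7.1e-12). Nucleotide synthesis reversed in De4 with EDTA (0.00489), in the EDTA difference (0.0130) and in De4zupT against De4 (0.0152). RNA polymerase did so in De4zupT against De4 (0.0304) and in the EDTA difference (0.0114). All of these list calls were lost with an estimated correlation (adjusted p = 0.486 for ribosomal proteins in De4). With normexp, ribosomal proteins reversed in the Zn difference De4zupT minus De4 (0.000418). Of genes, Rmet_6166 (−0.48), fliP (0.013) and Rmet_2151 (−0.59) reversed with slide as a block, and Rmet_1258 (−0.40) with the value table.

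Without 1 array, counts were 510 to 534, 875 to 986 and 750 to 797 for Zn, 43 to 68, 5 to 14 and 15 to 48 for EDTA, 449 to 581, 505 to 537 and 18 to 42 for the strains, 471 to 561, 8 to 24, 37 to 97 and 4 to 56 for the differences, and 10 to 10 for targeted genes. Same-numbered deviations correlated between −0.15 and 0.41 over 36 pairs of groups (mean 0.0751), so replicate numbers were not taken to pair the samples throughout. In 3 pairs, De4 and De4zupT untreated (0.16 to 0.39), De4 and De4zupT with Zn (0.22 to 0.26) and AE104 and De4 untreated (0.12 to 0.23), all 3 were over 0.1 and each array matched its own number best. With the replicate block the counts were 515, 924, 763, 46, 5, 42, 489, 507, 35, 503, 13, 49 and 13 in the order of the report's contrasts, and 44 lists. Signal over background limits dim genes, called with only a bound in 127 of 488 cases for De4 against AE104.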

Other observations

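The test of Zn against EDTA, its split by direction and all 3 versions of its bound against the hypothesis were tests chosen only after the result was seen.

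The tags around zur responded to Zn in a mixed way. The tag 3 numbers after zur, Rmet_0131, rose with Zn in all 3 strains, by log2 1.17 in AE104, 4.35 in De4 and 3.98 in De4zupT, and the tag 2 numbers after it, Rmet_0130, fell (−2.51, −3.02 and −2.67). In De4zupT the tags Rmet_0127 (−1.83), Rmet_0125 (−1.48) and Rmet_0124 (−1.18) were also called lower with Zn. The Zn effect differed from that in De4 for Rmet_0127 (−1.93) and Rmet_0125 (−1.30), and the test did not pass for Rmet_0124 (−0.58, adjusted p = 0.484). Of Rmet_0124 the EDTA differences were 2.04, 1.26 and 1.47. These tags were fixed as neighbours in number and have no names in the files.

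The run Rmet_1098 to Rmet_1103 was called in De4zupT in either direction. Its 6 genes were higher in untreated De4zupT than in AE104 (log2 2.30 to 3.78, and 1.83 to 4.36 with slide as a block, where 5 were called) and than in De4. They fell there with Zn, while 0 of the 6 were called with Zn in AE104 or De4 (limma, differences of −0.80 to −0.24 and −0.22 to 0.46). With EDTA in De4zupT the differences were 0.60 to 0.87 (−0.33 to 1.08 with slide as a block), and 0 were called in either fit. The run was chosen after its values were seen, and no explanation was tested.

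A hypothesis is that Zn and EDTA, as excess and removal of metal, move the same genes in opposite directions in AE104. Of the 46 genes called with EDTA, 28.3% had a Zn difference of the opposite sign, against 6.09% on average and at most 13.0% in 20 simulations of unchanged groups that share the untreated arrays, and 12 were called with Zn in the opposite and 10 in the same direction. The share was below the 60% set for the hypothesis and above the simulated values, so it is left undecided for the genes as a whole. Of the 35 genes higher with EDTA, 11.4% had the opposite sign, within the simulated range and below the 60%, and 3 were called in the opposite direction. The share argues against opposite movement for most of these 35, although the last bound leaves them undecided. The verdict depends on the bound. A first one of 40% counted against the hypothesis for all genes and for the 35. A second, the highest simulated share, did so for the 35 alone, and the last, which also asks for 0 called in the opposite direction, for neither. Of the 11 genes lower with EDTA, 81.8% had the opposite sign and 9 rose with Zn, cadA among them. Opposite movement may thus hold for this small group. It was separated after the first result and is open to the untreated arrays, whose SD reached 1.77 for Rmet_4596. The EDTA call of cadA was lost without any 1 of the 6 arrays. Some of the 11 genes have neighbouring tag numbers, such as Rmet_4596 and Rmet_4597, so they are not taken as independent.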
